A study of Rattus norvegicus with 15 samples.

How the data were processed

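Polyadenylated RNA of rat femurs was sequenced in 15 libraries of 5 groups, Sham, OVX, J, P and PJ, with 3 libraries each, and the groups were taken from the sample titles and treatment labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit, and whether strand was kept is not given in the sources used here. Per the submitters' processing notes, the tools were fastp 0.23.4, STAR 2.7.11a and featureCounts 2.0.6, and the genome build was mRatBN7.2. The deposited files give 1 value per gene for 30454 genes. The column that carries the title of the library and the word count holds FPKM (fragments per kilobase and library size), as the values themselves show, since they are not whole and depend on gene length. A further column named FPKM per the file headers was empty in all 15 files and was not used here. Gene names came from the files, 4319 genes had none, and none of these names was found in a RefSeq gene table of assembly GRCr8. As that build differs from the one named in the notes, no coordinates are given.

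Depth was inferred from the deposited FPKM values, which within a gene are whole multiples of what 1 read is worth. The effective length of each gene was taken as one that makes its values whole in all libraries, and 24049 of 24207 genes above 0 had such a length. At that length 100% of the values of genes with fewer than 10000 reads were whole within 0.05, which by this choice is not an independent check. Library totals in units of 1000000 reads were 34.4 to 61.0, and the recovered reads made up 99.885% to 99.981% of them. Even numbers made up 64.1% of recovered counts from 1 to 20, so both ends of a pair may have been counted, and the totals and the floor may be in read ends and not fragments. A floor of 3 reads corresponded to 0.0492 to 0.0873 reads per 1000000, which covers counting error only. Mitochondrial genes held 11.2% to 35.9% of the FPKM of a library and globin genes 0.084% to 8.25%.

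The following choices were made before the data were examined: groups, tests, filter, gene lists, the rule for named genes and the alternatives, except those named below as added. Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low values. Genes with a mean FPKM of at least 1 were tested, 14416 in number. A linear model over all 15 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow mean expression. It had 10 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were OVX against Sham, each treatment against OVX, PJ against J and against P, P against J, and PJ minus J minus P plus OVX for additivity, with an F test over the 5 groups. Standard errors (SE) are those of the fit, and means of FPKM are given with the standard deviation (SD) of 3 libraries.

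The 28 lists held 563 genes, of which 550 were matched to names in the files. They covered osteoblast and bone matrix, osteocyte, osteoclast, RANKL and osteoclast-promoting cytokines, the Wnt pathway, the BMP and TGF-beta pathway, estrogen receptors and responsive genes, interstitial matrix, cartilage, adipocyte, skeletal muscle, erythroid, neutrophil, B cell, T and NK cell, monocyte and macrophage, endothelial, megakaryocyte and platelet, mast cell with basophil and eosinophil, cell cycle, interferon response, inflammatory chemokines and cytokine signalling, immediate early and dissociation stress, cholesterol and fatty acid synthesis, aryl hydrocarbon receptor and NRF2 targets, oxidative phosphorylation, autophagy and lysosome, and apoptosis. Of each list, the members passing the gene test were counted over all tested genes and adjusted over the list alone. Lists were also tested with camera of limma, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the lists of a comparison.

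Named genes of the 4 main comparisons were the 10 with the highest and the 10 with the lowest fold change among those that passed, had a gene symbol and did not overlap between the groups, with the 5 of smallest p in a direction where fewer than 5 passed. To these came up to 4 members of each list with the smallest p and 12 bone, fat and osteoclast genes fixed by name (Esr1, Runx2, Sp7, Bglap, Col1a1, Sost, Ctsk, Acp5, Tnfsf11, Tnfrsf11b, Pparg and Adipoq). In the other comparisons they were the 5 of smallest p in each direction.

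Differences that share the OVX libraries were compared by the covariance across genes. It was set beside 2000 simulated draws in which groups did not differ, of which the central 95% is given, and beside the overlap of independent lists. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to TPM, median-ratio scaling, array weights, fits of only the groups compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, voom of limma on the recovered reads, a fit without mitochondrial and globin genes, a fit without P 2, a covariate of the erythroid and neutrophil level, and contrasts of each treatment against Sham were added.

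The procedure was tested on simulated data made for OVX against Sham with 14415 genes. Of changed genes, 58.2% of 67 were recovered at a fold of 2, 83.6% of 67 at 4 and 92.4% of 66 at 8. Of 166 calls, 10 (6.02%) were of unchanged genes. A shifted list had an adjusted p of 2.72e-38 in camera, and 0 of 100 random lists were called. In these simulated data the genes varied independently of each other, while the estimated correlation in the real erythroid list was 0.842. The calls of lists are therefore not tested here for correlated genes. In a separate simulation, 98 of 100 sets without effect had a covariance inside the simulated range. Some genes were left out of the named genes after the rule was applied and are not reported here. Globin and defensin genes with near-identical copies, and overlapping or antisense genes, have uncertain values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and numpy 2.4.6.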

Results

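Gene expression was measured by RNA sequencing of femurs from female SD rats in 15 libraries, 3 in each of 5 groups. The rats were 8 weeks old at the start, and treatment lasted 8 weeks after a 6-week recovery from surgery. Sham rats had fat removed near the ovaries, and OVX rats lost both ovaries, which removes the main source of estrogen. Sham and OVX rats were both given saline. Ovariectomised rats of group J received an extract of Juglans regia (walnut) at 1.6 g per kg per day, those of group P an extract of Psoralea corylifolia at 2.4 g per kg per day, and those of group PJ both extracts at 4.0 g per kg per day. The title of the study names osteoporosis after ovariectomy as the condition treated. The labels do not state that each library came from a separate rat, so the p-values measure the spread between these libraries. Library totals inferred from the deposited values in units of 1000000 reads ran from 34.4 (Sham 3) to 61.0 (PJ 2), and 19435 to 20845 genes were above 0 in a library. Pearson correlations across genes of log2(FPKM + 1) were 0.838 to 0.974 between libraries of one group and 0.587 to 0.967 between groups. Not all libraries were closest to their own group. P 2 had 0.903 with Sham 1, against 0.851 with P 1 and 0.838 with P 3. PJ 3 had 0.944 with P 1, against 0.899 with PJ 1 and 0.894 with PJ 2.

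In OVX against Sham, genes of blood-forming marrow were higher and genes of cartilage and connective tissue were lower. Hba-a1 (ENSRNOG00000029886), an alpha globin of red cells, had a mean FPKM of 29420 ± 4229 (SD, n = 3) in OVX and 987.6 ± 853.8 (SD, n = 3) in Sham. Mmp8, a collagenase of neutrophil granules, had 395.0 ± 73.5 against 11.9 ± 1.26 (SD, n = 3 each), and the platelet chemokine Ppbp had 709.7 ± 270.9 against 5.91 ± 5.12. Hba-a1 was chosen here and under J after its values were seen. In the other direction, Prg4 (ENSRNOG00000002385), the lubricin of joint surfaces, had 3.62 ± 3.29 in OVX against 4771 ± 2386 in Sham (SD, n = 3 each).

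All 19 tested erythroid genes rose, with a median log2 fold change of 5.46, among them Slc4a1 (6.79 ± 0.57, SE) and Ahsp (7.01 ± 0.65), which code for a red cell membrane protein and a globin chaperone. The 21 neutrophil and granule genes also all rose (median 5.08), led by the defensins Defa5 (8.74 ± 0.67), Np4 (8.60 ± 0.65) and RatNP-3b (8.57 ± 0.73). The 14 megakaryocyte and platelet genes rose (median 4.66), as did the 24 cell cycle genes (median 3.82), including the proliferation marker Mki67 (5.45 ± 0.25). Of 20 B cell genes, 15 rose and 5 did not pass, with Igll1 at 4.50 ± 0.65 and Pax5 at 2.51 ± 0.40. Adjusted over the list alone, the same numbers passed in these 5 lists. The adjusted p of these lists in camera was 0.414 with an estimated correlation for the first 4 and 0.636 for B cells. Globin and defensin genes have near-identical copies, and the values of single copies are uncertain.

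All 14 cartilage genes fell in OVX (median log2 fold change -6.30), including Acan (-8.24 ± 1.68, SE), Col10a1 (-8.55 ± 2.06), Chad (-9.61 ± 1.83) and Ucma (-8.24 ± 1.70). The lowest value of all named genes was that of Clec3a, a cartilage lectin, at -11.28 ± 2.39. Of 25 genes of the interstitial matrix, 24 fell (median -3.37), such as Col6a2 (-3.21 ± 0.25) and Bgn (-2.96 ± 0.28). Of 14 endothelial genes, 13 fell (median -2.41), with Eng at -2.23 ± 0.22, and of 27 genes of the BMP and TGF-beta pathway, 21 fell, with the BMP antagonist Nog at -2.13 ± 0.25. When adjusted over the list alone, 14, 24, 13 and 22 fell in these 4 lists. The adjusted p in camera was 0.628 for cartilage, 0.414 for matrix, 0.414 for endothelium and 0.528 for the BMP list with an estimated correlation.

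Few genes of bone cells passed in OVX against Sham. Of 18 osteoblast and bone matrix genes, 6 fell and 1 rose, with Sparc at -3.18 ± 0.40 (SE), Col5a2 at -3.33 ± 0.44 and the mineralisation phosphatase gene Phospho1 at 1.91 ± 0.23. The osteoblast regulators Runx2 (-0.79 ± 0.50) and Sp7 (-1.01 ± 0.61) and the bone collagen Col1a1 (-1.70 ± 1.00) did not pass. Neither did the osteoclast genes Ctsk (-1.60 ± 1.06) and Acp5 (-0.24 ± 1.03), nor Sost (1.27 ± 2.26). Sham 3 had a Ctsk FPKM of 1494, against 65.8 in Sham 1 and 60.3 in Sham 2, and a Sost FPKM of 312.8 against 0.28 and 0.43. Of 17 osteoclast genes, 3 rose and 2 fell, and of 11 osteocyte genes 1 fell. Among regulators of osteoclasts, the decoy receptor Tnfrsf11b fell (-5.94 ± 1.10), while its ligand Tnfsf11 did not pass (-0.55 ± 0.62). Esr1, the estrogen receptor gene, was under the filter on low values and was not tested.

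Over all 14416 tested genes, limma called 3650 higher and 4163 lower in OVX than in Sham at an adjusted p of 0.05. The larger side depended on the scale: 4308 were higher and 3950 lower with median-ratio scaling, 2968 and 2759 at a mean FPKM of at least 5, and 3114 and 4746 after rescaling to TPM. In the same test on lists, camera with the preset correlation called 13 of 28 lists, and none with an estimated correlation. Regrouping the same 6 libraries in other ways gave up to 18 called lists. Each regrouping keeps part of the difference between the groups. These counts therefore do not show what chance alone gives, or that the 13 lists exceed it.

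**Figure D1:**
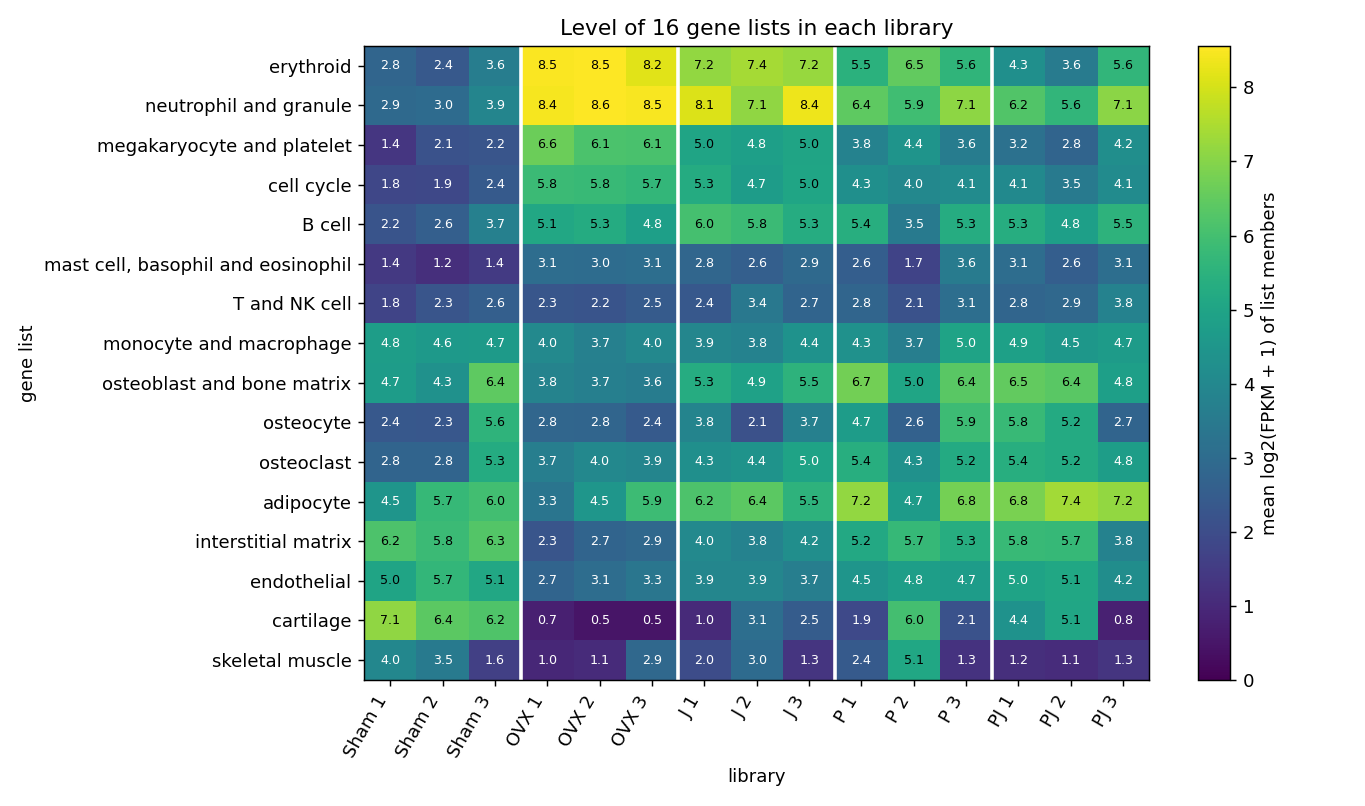
Level of 16 gene lists in each library, as the mean log2(FPKM + 1) of the tested members (rows, lists; columns, libraries in 5 groups of 3). The cartilage list was at 6.2 to 7.1 in the Sham libraries and at 0.5 to 0.7 in the OVX libraries, and the erythroid list at 2.4 to 3.6 and 8.2 to 8.5.

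J against OVX asks what the walnut extract changed after ovariectomy. Some platelet and cell cycle genes and 2 red cell genes were lower and some connective tissue genes were higher than in OVX. Tubb1, the tubulin of platelets, had a mean FPKM of 24.6 ± 4.90 in J against 79.6 ± 11.9 in OVX (SD, n = 3 each), a log2 fold change of -1.66 ± 0.39 (SE). Mmp2, a matrix protease, had 23.4 ± 3.82 against 4.21 ± 0.35, a log2 fold change of 2.22 ± 0.53. Hba-a1 had 15150 ± 1984 in J, between the OVX and Sham means, but did not pass in J against OVX.

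Of the 14 megakaryocyte and platelet genes, 5 fell, including Gp6 (-1.61 ± 0.33) and P2ry12 (-0.81 ± 0.15). The platelet-related Mmrn1 (-1.95 ± 0.33), F5 (-1.73 ± 0.22) and Pde5a (-1.71 ± 0.23) fell as well. Of 19 erythroid genes 2 fell, with Bpgm at -1.08 ± 0.26, and of 24 cell cycle genes 9 fell, such as Pcna (-0.81 ± 0.18). None of the 21 neutrophil genes passed. Of 25 matrix genes 7 rose, such as Col3a1 (1.91 ± 0.51), Bgn (1.44 ± 0.28) and Timp1 (1.67 ± 0.35), and of 18 osteoblast genes 2 rose, Sparc (1.80 ± 0.40) and Col5a2 (1.73 ± 0.44). Of 14 endothelial genes 2 rose, Egfl7 (1.18 ± 0.24) and Tie1 (0.71 ± 0.19). Other genes that rose were Mt3 (3.02 ± 0.77), a metallothionein, Serpinf1 (2.25 ± 0.59) and the cytokine Il34 (1.87 ± 0.31), a ligand of the macrophage receptor Csf1r. None of 20 adipocyte, 17 osteoclast or 14 cartilage genes passed, and Col1a1 (2.72 ± 1.00), Ctsk (2.76 ± 1.06) and Adipoq (2.20 ± 1.07) did not either. Adjusted over the list alone, 13 platelet, 7 erythroid and 20 cell cycle genes fell and 11 matrix, 8 endothelial and 9 osteoblast genes rose, while 1 osteoblast gene fell. The adjusted p of these lists was 0.610 for platelets and cell cycle and 0.798 for the other 4 with an estimated correlation.

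In limma, 471 genes were higher and 402 lower in J than in OVX. This count rested on single libraries: it was 22 without OVX 1, 88 without OVX 2, 246 without J 1 and 96 without J 3, each with more genes lower than higher. With median-ratio scaling, 420 were higher and 949 lower, after rescaling to TPM 207 and 221, and in voom on recovered reads 376 and 388. More genes were higher at a pseudocount of 0.1 (688 and 334), without mitochondrial and globin genes (649 and 396), with array weights (2734 and 1200), without OVX 3 (580 and 324) and without J 2 (477 and 248).

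P against OVX asks the same of the Psoralea extract. Red cell, platelet, neutrophil and cell cycle genes were lower than in OVX, and matrix, endothelial, osteoblast and some osteoclast genes were higher. Hba-a1 had a mean FPKM of 4588 ± 2487 in P against 29420 ± 4229 in OVX (SD, n = 3 each). Ctsk, the main collagen-degrading protease of osteoclasts, had 1052 ± 680.4 against 67.9 ± 40.6, and Sparc, a bone matrix glycoprotein, had 1231 ± 577.2 against 155.1 ± 31.7.

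All 19 erythroid genes fell in P (median log2 fold change -2.57), such as Slc4a1 (-2.72 ± 0.57, SE), and all 14 platelet genes fell (median -2.49), such as Ppbp (-3.09 ± 0.64) and Treml1 (-2.75 ± 0.45). Of 21 neutrophil genes 20 fell (median -2.07), with Mmp8 at -1.77 ± 0.35, and all 24 cell cycle genes fell (median -1.63), with Mki67 at -1.97 ± 0.25. None of 20 B cell genes passed. Of 25 matrix genes 23 rose (median 2.67), such as Fmod (4.73 ± 1.12), Thbs4 (4.54 ± 1.16) and Dcn (4.39 ± 1.11). P 2 stood apart in these genes, with a Dcn FPKM of 3996 against 225.2 in P 1 and 219.5 in P 3 and a Fmod FPKM of 302.1 against 24.6 and 29.3, while Thbs4 was lower in P 2 (22.15 against 108.0 and 79.1). Of 14 endothelial genes 13 rose, with Emcn, a marker of bone sinusoids, at 2.24 ± 0.38. Of 18 osteoblast genes 13 rose and 1 fell. Spp1 (4.75 ± 1.02), Col1a1 (3.07 ± 1.00), Sp7 (2.27 ± 0.61) and Runx2 (1.40 ± 0.50) were among those that rose, and Bglap, the osteocalcin gene, did not pass (3.32 ± 1.65). Of 17 osteoclast genes 9 rose and 1 fell. Ctsk (3.83 ± 1.06), Acp5 (2.93 ± 1.03) and Tnfrsf11a (2.71 ± 0.43), the receptor that starts osteoclast formation, rose, and Car2, which red cells also carry, fell (-2.34 ± 0.60). Tnfrsf11b rose (4.07 ± 1.10) and Tnfsf11 did not pass (1.14 ± 0.62). Of 11 osteocyte genes 3 rose, and none when adjusted over the list alone (adjusted p 0.863 with an estimated correlation), and Sost did not pass (0.58 ± 2.26).

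Of 27 genes of the Wnt pathway 12 rose in P, such as Axin2 (1.06 ± 0.14), a feedback target of the pathway, and the secreted inhibitors Wif1 (3.21 ± 0.62) and Dkk3 (2.86 ± 0.48). Of 27 genes of the BMP and TGF-beta pathway 18 rose and 1 fell, with Bmpr1a at 2.43 ± 0.36. Of 20 adipocyte genes 6 rose, with Pparg at 1.36 ± 0.47, and Adipoq did not pass (2.72 ± 1.07). Of 14 cartilage genes 5 rose, with Chad at 5.49 ± 1.83, and the joint genes Prg4 (5.39 ± 1.31) and Cilp (5.19 ± 1.15) rose too. One library carried most of the cartilage signal: the list was at 5.99 in P 2 and at 1.87 and 2.15 in P 1 and P 3, and the muscle list at 5.11 against 2.43 and 1.27. The osteoblast list was at 5.05 in P 2 against 6.72 and 6.39, and the osteocyte list at 2.65 against 4.74 and 5.88. The adipocyte list was at 4.69 in P 2, inside the range of the OVX libraries (3.32 to 5.87), against 7.16 and 6.76. Mitochondrial genes made up 35.9% of the FPKM of P 2, against 17.6% and 11.2%. When adjusted over the list alone, 19 erythroid, 14 platelet, 21 neutrophil and 24 cell cycle genes fell, and 23 matrix, 13 endothelial, 15 osteoblast, 11 osteoclast, 13 Wnt, 18 BMP, 6 adipocyte and 6 cartilage genes rose, while 1 osteoblast, 1 osteoclast and 1 BMP gene fell. The adjusted p with an estimated correlation was 0.467 for the erythroid, platelet, neutrophil, cell cycle, matrix and endothelial lists, 0.650 for the BMP list, 0.701 for the Wnt list, 0.741 for osteoblasts, 0.811 for cartilage, 0.845 for adipocytes and 0.863 for osteoclasts.

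In limma, 3486 genes were higher and 2160 lower in P than in OVX. With median-ratio scaling, 2790 were higher and 3390 lower.

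**Figure D2:**
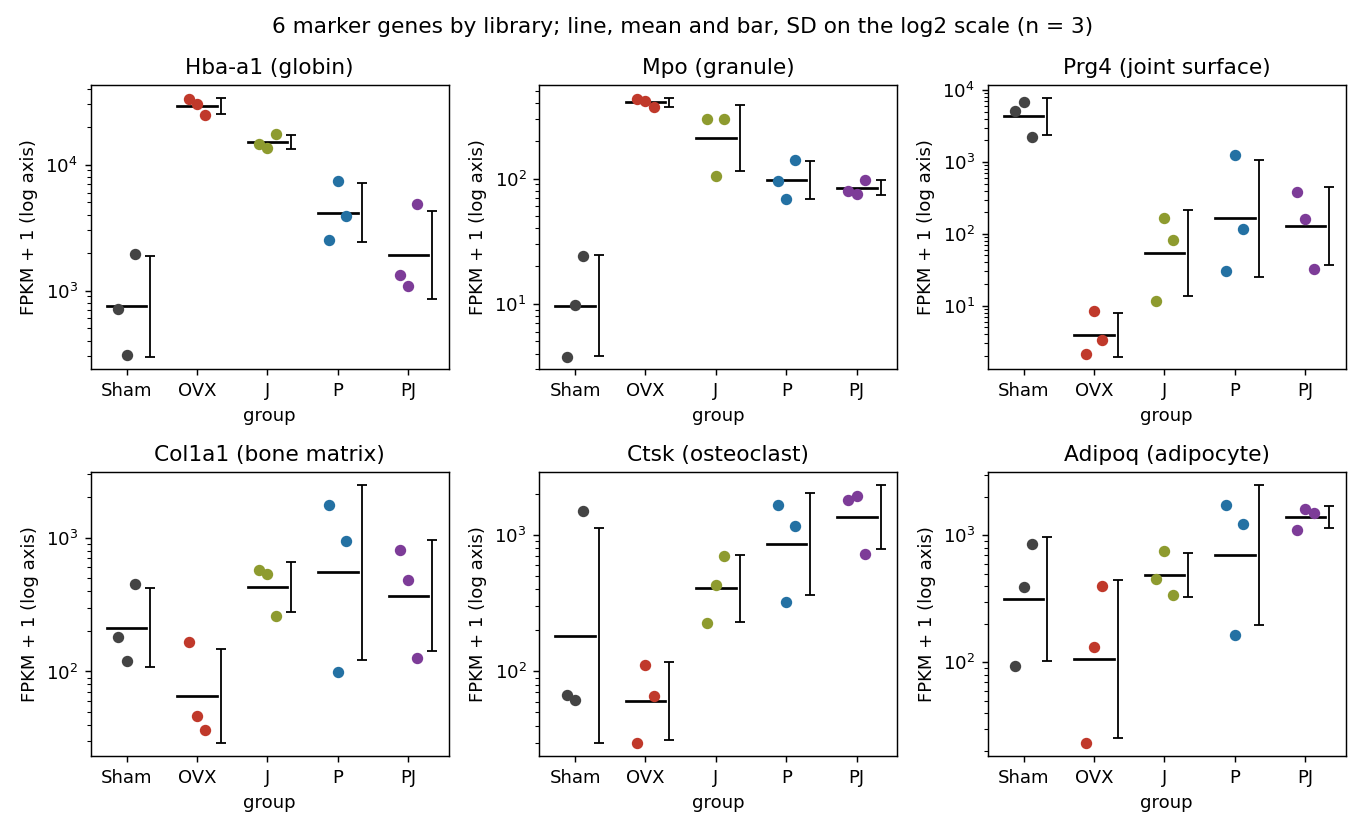
FPKM + 1 (log axis) of 6 marker genes in the 15 libraries by group, with the mean and SD on the log2 scale (n = 3). Mean FPKM of Hba-a1 was 29420 in OVX and 2418 in PJ, and that of Ctsk 67.9 and 1482.

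PJ against OVX asks what the combination changed. Blood-forming genes were lower and adipocyte, matrix, endothelial and some bone cell genes were higher than in OVX. Slc4a1, the anion exchanger of red cells, had a mean FPKM of 49.1 ± 46.5 in PJ against 799.9 ± 105.1 in OVX (SD, n = 3 each). Ctsk had 1482 ± 657.7 against 67.9 ± 40.6, and Adipoq, the adipocyte hormone gene, had 1405 ± 268.3 against 183.5 ± 193.6.

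All 19 erythroid genes fell in PJ (median log2 fold change -4.03), with Ahsp at -4.66 ± 0.65 (SE) and Ermap at -4.21 ± 0.45. All 14 platelet genes fell (median -3.16), such as Tubb1 (-3.41 ± 0.39), as did 20 of 21 neutrophil genes (median -2.45), such as Prtn3 (-2.69 ± 0.49), and all 24 cell cycle genes (median -1.86). Of 20 adipocyte genes 18 rose (median 2.57), such as Scd (4.65 ± 1.38), Adipoq (3.70 ± 1.07), Plin4 (3.21 ± 0.68) and Pparg (2.12 ± 0.47). Of 25 matrix genes 22 rose, with Bgn at 2.62 ± 0.28, and of 14 endothelial genes 13 rose, with Egfl7 at 2.21 ± 0.24. Of 18 osteoblast genes 12 rose and 1 fell. Spp1 (4.78 ± 1.02), Sp7 (2.23 ± 0.61) and Runx2 (1.69 ± 0.50) rose, Phospho1 fell (-1.38 ± 0.23), and Col1a1 (2.49 ± 1.00) and Bglap (3.00 ± 1.65) did not pass. Of 17 osteoclast genes 10 rose and 1 fell, with Ctsk at 4.50 ± 1.06, the proton pump subunit Atp6v0d2 at 3.95 ± 1.02 and Acp5 at 3.44 ± 1.03. Both Tnfsf11 (1.92 ± 0.62) and Tnfrsf11b (3.18 ± 1.10) rose. Of 11 osteocyte genes 3 rose, and 2 when adjusted over the list alone (adjusted p 0.767 with an estimated correlation), and Sost did not pass (1.37 ± 2.26).

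Of 27 Wnt genes 12 rose in PJ, with Tcf7l2 at 1.82 ± 0.23, and of 27 BMP and TGF-beta genes 19 rose, with Smad7 at 1.98 ± 0.28. Of 14 cartilage genes 5 rose, with Chad at 5.19 ± 1.83, and Prg4 (5.01 ± 1.31) and Cilp (4.83 ± 1.15) rose. The cartilage list was at 4.37 in PJ 1, 5.06 in PJ 2 and 0.77 in PJ 3. PJ 3 was also lower in the osteoblast list (4.84 against 6.52 in PJ 1 and 6.38 in PJ 2), the osteocyte list (2.74 against 5.77 and 5.22) and the matrix list (3.80 against 5.75 and 5.74). None of the 20 B cell genes other than Ebf1 (0.91 ± 0.22) passed. Adjusted over the list alone, 19 erythroid, 14 platelet, 21 neutrophil and 24 cell cycle genes fell, and 18 adipocyte, 23 matrix, 13 endothelial, 15 osteoblast, 11 osteoclast, 15 Wnt, 20 BMP and 2 cartilage genes rose, while 1 osteoblast, 1 osteoclast and 1 BMP gene fell. The adjusted p with an estimated correlation was 0.358 for the erythroid, platelet and cell cycle lists, 0.530 for neutrophils, 0.581 for matrix and endothelium, 0.654 for the Wnt and BMP lists, 0.717 for adipocytes and osteoblasts, and 0.767 for osteoclasts and cartilage.

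In limma, 4298 genes were higher and 2103 lower in PJ than in OVX. With median-ratio scaling, 2992 were higher and 3575 lower. The median log2 fold change of all tested genes was 0.22, and this scaling moved it by -0.25.

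**Figure D3:**
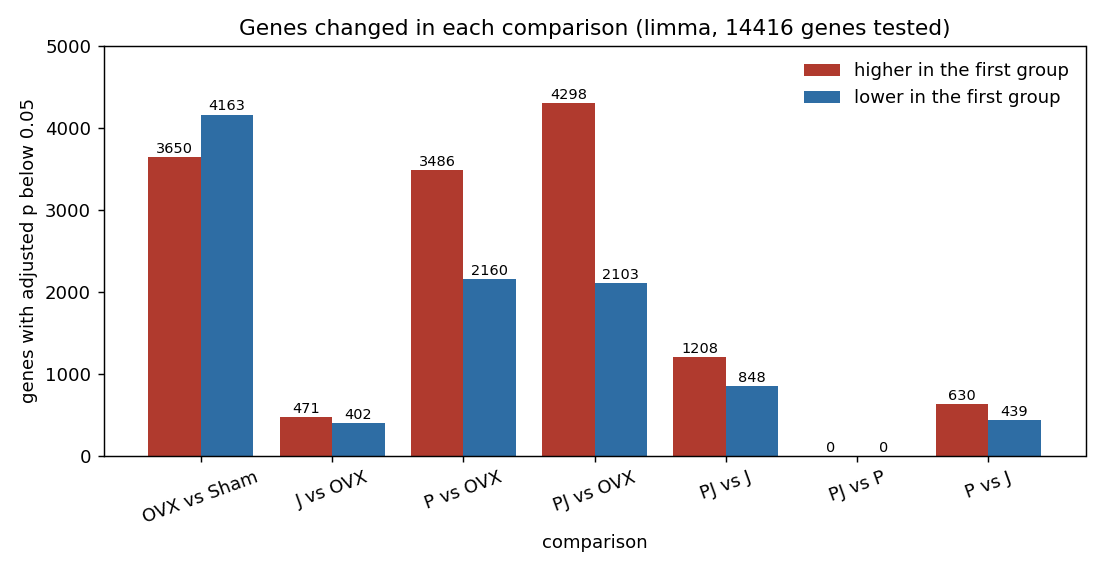
Number of genes higher (red) and lower (blue) in the first group of each comparison at an adjusted p of 0.05 in limma. The counts for PJ against P are 0 and 0, and those for OVX against Sham are 3650 and 4163.

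The changes under treatment ran opposite to those after ovariectomy. Of the genes called in OVX against Sham, 3351 that fell rose in PJ and 1997 that rose fell in PJ, against 1241 and 532.5 for independent lists. In P these numbers were 3172 and 2079, against 1007 and 546.9, and in J they were 456 and 379, against 136 and 101.8. Genes such as Slc4a1, Mki67, Bgn and Chad were called in both comparisons with opposite signs in P and PJ. The OVX libraries enter both differences and alone produce some opposition. The covariance across genes was -0.49 for J, -1.15 for P and -1.18 for PJ. Values simulated for unchanged groups that share these libraries averaged -0.06 in each case, and their central 95% ran from -0.22 to 0.03 for J, -0.22 to 0.03 for P and -0.23 to 0.03 for PJ. The correlation was -0.68 for J, -0.91 for P and -0.86 for PJ, and only that of P lay outside its simulated range (-0.89 to 0.31, -0.90 to 0.31 and -0.90 to 0.33). These values run across genes, which are not independent replicates. The slope on the ovariectomy change was -0.26 for J, -0.59 for P and -0.61 for PJ.

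The treatments also moved the same genes in the same direction. P and PJ shared 3275 genes that rose and 1883 that fell, against 1039 and 315.1 for independent lists, and J shared 464 and 387 with P and 468 and 387 with PJ, against 113.9 and 60.2 and 140.4 and 58.6. The covariance was 0.84 between P and PJ, 0.43 between J and PJ and 0.39 between J and P, and the simulated values averaged 0.06 in all 3 pairs, with a highest upper bound of 0.22. The correlation was 0.94 between P and PJ, above a simulated range that ended at 0.90, and 0.83 between J and PJ and 0.82 between J and P, both inside ranges that ended at 0.90. With 3 OVX libraries the controls could not be split, and part of the excess in shared calls may come from them.

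PJ differed from J in 2056 genes, and from P in none in the main fit. Bpgm, a red cell enzyme, was lower in PJ than in J (log2 fold change -2.37 ± 0.26, SE), with a mean FPKM of 37.7 ± 14.3 against 191.2 ± 20.6 (SD, n = 3 each). Trim59 (-1.73 ± 0.22) and the centromere gene Cenpk (-1.33 ± 0.17) were lower too, and Plcg1 (1.10 ± 0.15), Cdc42bpb (1.24 ± 0.19) and Parp3 (1.22 ± 0.19) were higher. Of 19 erythroid genes 18 were lower in PJ than in J, of 24 cell cycle genes 21 and of 21 neutrophil genes 11, with an adjusted p of 0.325, 0.325 and 0.446 with an estimated correlation. When adjusted over the list alone, these numbers were 19, 24 and 17. The count was 843 without J 1, 925 without J 3, 612 without PJ 1, 397 without PJ 2 and 3821 without PJ 3, and more genes were lower than higher without J 2, PJ 1 or PJ 2. It was split as 1208 higher and 848 lower, as 1725 and 563 after rescaling to TPM, and as 658 and 1465 with median-ratio scaling.

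P differed from J in 1069 genes, of which 630 were higher in P. The chemokine receptor gene Cxcr4 was lower in P (-1.22 ± 0.18), with a mean FPKM of 69.7 ± 7.93 against 162.8 ± 6.94 (SD, n = 3 each), and so were Bpgm (-1.47 ± 0.26) and the survival gene Bcl2l1 (-0.86 ± 0.15). Parp3 (1.34 ± 0.19) and Efna1 (0.91 ± 0.15) were higher. Of 24 cell cycle genes 12 were lower in P, and 24 adjusted over the list alone, with an adjusted p of 0.563 with an estimated correlation. The smallest adjusted p in limma was 0.036, and the count was 0 without J 1, J 3, P 1 or P 3 and 328 without J 2, of which 89 were higher. It was 0 after rescaling to TPM, and with median-ratio scaling 518 were higher and 844 lower.

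Between PJ and P, limma called 0 genes, with 296 (2.05% of those tested) at an unadjusted p under 0.05. With voom on recovered reads the count was also 0, and limma with array weights called 4. The libraries of PJ and P did not overlap in 4.02% of genes, against 10% by chance. Both shares are below those of chance, so the 0 does not show that PJ and P are alike. Among the genes with the smallest p were the acute-phase gene Hp, with a mean FPKM of 27.7 ± 5.94 in PJ and 7.77 ± 1.90 in P (SD, n = 3 each; log2 difference 1.71 ± 0.39, SE), S1pr5 (0.65 ± 0.17) and Minpp1 (-0.74 ± 0.19), each with an adjusted p of 1.00 in limma. Red cell genes Ermap (-1.63 ± 0.45) and Epb42 (-1.51 ± 0.42) had lower values in PJ without passing. Adjusted over the list alone, 16 of 19 erythroid genes were lower in PJ than in P (median log2 fold change -1.40), and none over all genes. The libraries overlapped, since the erythroid list was at 5.64 in PJ 3, against 4.26 in PJ 1 and 3.57 in PJ 2, and at 5.48, 6.51 and 5.60 in P 1 to P 3. The adjusted p of the erythroid list in camera was 1.71e-37 with the preset correlation and 0.1499 with an estimated correlation.

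The dose of PJ is the sum of the single doses, and the contrast of PJ with the sum of the J and P changes tests whether they add on the log2 scale. limma called 0 genes, with 1332 at an unadjusted p under 0.05, and voom on recovered reads also called 0. With array weights limma called 920 (299 higher and 621 lower), at a pseudocount of 0.1 and at a mean FPKM of at least 5 it called 2 each, after rescaling to TPM 1, without OVX 3 it called 6 and without P 3 it called 1. The gene with the smallest p was Efna1, an ephrin ligand, at -1.60 ± 0.21 (SE) with an adjusted p of 0.053. Its mean FPKM was 2.69 ± 0.21 in OVX, 8.94 ± 0.60 in J, 17.8 ± 3.58 in P and 15.6 ± 1.32 in PJ (SD, n = 3 each). Other named genes were Pdgfa (-1.78 ± 0.29), Nab2 (-1.28 ± 0.21), Evc2 (2.08 ± 0.37) and Pde5a (1.54 ± 0.32), none of which passed in limma. When adjusted over the list alone, 8 of 25 matrix and 2 of 18 osteoblast genes had less than the sum, with an adjusted p of 0.857 for both lists with an estimated correlation. PJ 3 was the lowest PJ library in both lists, and without it camera with the preset correlation called 6 lists for this contrast and not 11 (7 without J 2). Over the 5 groups together, the limma F test called 7213 of 14416 genes.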

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

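The fits with voom, without mitochondrial and globin genes, without P 2 and with the blood-cell covariate were chosen after the data were seen, and the others were planned. Where a value moved, the cause was not tested. The genes changed in OVX against Sham, P against OVX and PJ against OVX stayed within 1.5 times 7813, 5646 and 6401 under every alternative except the covariate. All 102 alternative values of the 6 covariances kept their sign and stayed beyond the simulated range. Leaving out 1 library of the groups compared gave 6715 to 7354 genes for OVX against Sham, 4133 to 5799 for P against OVX and 4892 to 6551 for PJ against OVX. The ranges were 22 to 904 for J against OVX, 397 to 3821 for PJ against J, 0 to 859 for P against J and 0 for PJ against P. Additivity had 0 to 6 genes and 6 to 13 lists, and the F test 5821 to 8357 genes. In contrasts without group P, the fit without P 2 gave 8215 genes for OVX against Sham and 1255 for J against OVX. It gave 7014 for PJ against OVX and 2716 for PJ against J. J against OVX had 873 genes, with 540 without a filter, 428 under TPM and 1369 under median-ratio scaling. P against J had 1069, with 515 at a pseudocount of 0.1 and 0 in limma without a filter (4934 at an unadjusted p under 0.05), under TPM (3890) and with only the groups compared (3348). PJ against J had 2056, and 616 genes and 16 lists with only the groups compared. Additivity had 0, with 2 at a pseudocount of 0.1, 2 at a mean FPKM of at least 5 and 1 under TPM. Array weights gave 3934 for J against OVX, 7405 for PJ against J, 4197 for P against J, 4 for PJ against P, 920 genes and 7 lists for additivity and 11810 for the F test. With the correlation estimated, camera called 0 lists in each of the 8 comparisons. Scaling moved the median log2 fold change of all genes by -0.12 (OVX against Sham), 0.14 (PJ against OVX), 0.18 (PJ against J) and 0.13 (additivity) under TPM, and by -0.10 (J), -0.17 (P) and -0.25 (PJ against OVX) and -0.15 (PJ against J) under median ratio. voom called 7596 genes for OVX against Sham, 764 for J, 5510 for P and 6391 for PJ against OVX. Replicate numbers did not pair the libraries: 9 of 30 pairs of the same number correlated above 0.1, the median was -0.00694, and 5 libraries were closest to their own number. With the replicate block the counts were 7769, 792, 5644 and 6392 for OVX against Sham and for J, P and PJ against OVX, 1972 for PJ against J, 917 for P against J and 0 for PJ against P and additivity, and no count moved by 1.5 times. The covariate, which follows the groups closely, left 0 genes in limma for OVX against Sham, P and PJ against OVX (1246, 2603 and 2552 at an unadjusted p under 0.05) and 328 for J against OVX. Single genes were followed only where named for their fold change, and the named list members and the genes fixed by name were not. Under the covariate 23 of these values changed sign without passing. In OVX against Sham these were Ahsp -1.23, Slc4a1 -0.16, Car1 -1.54, Hemgn -1.05, Clec3a 9.27, Cytl1 3.00, Chad 4.19, Ecrg4 5.31, Col10a1 6.36, Ucma 4.68 and Acan 5.17. In P against OVX they were Chad -0.35, Ecrg4 -0.79, Comp -0.22, Hbb 0.22, Hba-a1 0.60, Rhd 0.045, Slc4a1 0.22 and Hba-a3 0.55, and in PJ against OVX Ecrg4 -2.96, Chad -2.58, Cytl1 -2.35 and Car1 0.36. No other gene followed changed sign under any alternative.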

Other observations

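Tests of marrow share, joint tissue, mixture, bone share and depth, and the joint test against both Sham and OVX, were chosen after the results were seen, and those on other splits of the libraries before. Among gene groups not described so far, the aryl hydrocarbon receptor and NRF2 list went both ways. Of its 16 members, 4 rose and 9 fell in OVX against Sham, and 8 rose and 5 fell in PJ against OVX. Gclm had log2 fold changes of 2.75 ± 0.17 (SE, n = 3 each) and -2.16 ± 0.17, and Gclc 2.09 ± 0.19 and -1.89 ± 0.19, while the receptor gene Ahr had -1.49 ± 0.18 and 1.41 ± 0.18. Of 8 estrogen-responsive genes, 3 fell in OVX and 4 rose in PJ, led by the cyclin gene Ccnd1 (-2.41 ± 0.22 and 2.12 ± 0.22). Camera with the preset correlation called this list in neither comparison (adjusted p 0.231 and 0.0784). Of all 14416 tested genes, 3650 rose and 4163 fell in OVX against Sham, and 4298 rose and 2103 fell in PJ against OVX. The counts of this and the next paragraph are to be read beside these. Of 20 apoptosis genes, 7 rose and 4 fell in OVX, with the survival genes Bcl2l1 at 1.44 ± 0.15 and Bcl2 at -1.69 ± 0.27. Of 28 oxidative phosphorylation genes, 15 rose and 1 fell in OVX (17 and 1 adjusted over the list alone), with Cox5a at 1.60 ± 0.22. Of 20 autophagy and lysosome genes, 3 rose and 7 fell, with Gabarapl1 at -2.08 ± 0.21.

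Immune lists went both ways. Of 18 T and NK cell genes, 2 rose and 1 fell in OVX, with the NK granule gene Nkg7 at 3.55 ± 0.39 (SE), and 10 rose and 1 fell in PJ against OVX. The median over these genes in OVX was -0.05 and the mean 0.13, which differ in sign, as they do for osteoclast genes (-0.24 and 0.26). Of 16 monocyte and macrophage genes, 2 rose and 5 fell in OVX, with Cx3cr1 at -1.68 ± 0.24. Of 14 genes of mast cells, basophils and eosinophils 7 rose, with Ms4a2 at 4.37 ± 0.45. Of 19 interferon genes, 7 rose and 4 fell, with Rsad2 at 5.09 ± 0.40 and Ifi44 at -1.48 ± 0.20. Of 19 inflammatory genes, 4 rose and 4 fell, with Icam1 at -1.66 ± 0.19. Of 15 immediate early and stress genes, 1 rose and 8 fell, with Hspb1 at -4.01 ± 0.47. Of 21 cholesterol and fatty acid genes, 6 rose and 2 fell. Of 10 genes of the RANKL list, 1 rose and 4 fell in OVX and 6 rose in PJ against OVX, with Csf1 at 1.56 ± 0.33. Of 27 Wnt genes, 1 rose and 12 fell in OVX, and of 20 adipocyte genes 1 fell. Of 20 skeletal muscle genes, 3 fell, and P 2 had an Acta1 FPKM of 695.3.

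A first pattern is the rise of blood-forming genes and the fall of cartilage genes in OVX. If a higher marrow share were the whole cause, lists of cells found in marrow alone would rise alike, which was tested with a pseudocount of 0.1. B cell genes rose by 2.76 ± 0.58 (SE, log2) less than the mean of the erythroid, neutrophil and megakaryocyte lists. T and NK cell genes rose by 5.37 ± 0.47 less than that mean. This goes against a marrow share only if B, T and NK cell genes come from marrow alone. Where they come from was not tested, so no conclusion is drawn for these cells. The 3 lists themselves differed by at most 0.859 ± 0.424, so for them a marrow share and a change in the marrow cannot be told apart with 3 libraries a group. The cartilage list ranged by 5.80 within PJ, a share of 0.740 of the distance of 7.84 between Sham and OVX, so joint tissue left on some pieces may contribute to differences in the treated groups. Within Sham and OVX the shares were 0.119 and 0.0696, so no difference between pieces as large as in PJ is seen there. The list still ranged by 0.931 within Sham. In OVX its values were low, where differences between pieces would hardly show. Joint tissue kept on all Sham pieces and on no OVX piece would not show in these shares. It cannot be told apart here from an effect of ovariectomy, and both stay open as untested.

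The opposite direction of treatment and ovariectomy changes is a second pattern. The covariances of -0.494 (J), -1.15 (P) and -1.18 (PJ) lie below the ranges simulated for unchanged groups, though of the correlations only that of P did. OVX and Sham do differ here, and spread between libraries along that difference is not in the simulation. How much of the opposition comes from the shared OVX libraries is therefore not settled. If treated femurs were a mixture of OVX-like and Sham-like tissue, genes higher and genes lower in OVX would give the same Sham-like share. The shares differed by 0.191 (SD 0.132) in J, 0.156 (SD 0.047) in P and 0.147 (SD 0.103) in PJ (n = 3 each). They were above 0 in all 9 treated libraries (0.0588 to 0.332), with a one-sample t test p of 0.130, 0.0291 and 0.132 (adjusted over the 3 groups 0.132, 0.0872 and 0.132). The 9 values share the same OVX and Sham means and the adjusted p values miss 0.05 with 3 libraries a group, so unequal shares are not established. A mixture and an effect of treatment cannot be told apart here, and the effect of treatment stays open as untested.

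The spread of bone cell genes within groups is the last pattern. Deviations of the osteoblast list from the group means followed those of the osteoclast list across 15 libraries (Pearson r 0.858, permutation p 0.00887, adjusted 0.0266; Spearman rho 0.857, permutation p 0.00823, adjusted 0.0247), and r was 0.857 without the 2 libraries farthest from the median. Osteocyte and osteoclast lists gave r 0.804 (permutation p 0.0225, adjusted 0.0338) and rho 0.736 (p 0.0234, adjusted 0.0351), with r 0.764 without 2 libraries. A differing share of bone in the pieces may explain this, and depth gave r -0.0252 (permutation p 0.948) and rho -0.0393 for the osteocyte list, in a family of 3 relations with 7776 permutations within groups. Biological differences between animals stay open as untested.

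Each split of 6 libraries into 3 and 3 has 10 forms, too few for a share under 0.05. Every split but the real one puts unequal numbers of the groups on each side, so part of the difference between groups stays in it. Its counts of genes and lists are not those of chance alone. The real split gave the highest count of genes (1 of 10) in OVX against Sham (7813, next 0), J against OVX (873, next 1), P against OVX (5646, next 1), PJ against OVX (6401, next 0), PJ against J (2056, next 597) and P against J (1069, next 1). For PJ against P the real count was 0, which all 10 reach whatever the data, with up to 39. Lists called by camera were as many in 10 of 10 splits for OVX against Sham (13, highest other 18), 5 for J (11, 16), 10 for P (12, 16) and 6 for PJ against OVX (11, 15), 3 for PJ against J (10, 17), 3 for PJ against P (14, 16) and 10 for P against J (10, 15). For additivity the real count of genes was 0, which 100 of 100 random splits reach whatever the data, so it decides nothing. For its 11 lists 64 of 100 splits gave as many, with up to 19. These splits mix libraries of groups that differ, so they do not show what chance alone gives, and chance is not excluded for the lists. Splits called up to 4494 genes, with OVX 1, OVX 3 and J 1 in the place of PJ. Differences between the groups enter such splits, and their part in this count was not tested. For the F test 1 of 100 splits, the real one, gave 7213 genes, with 3403 the highest other. A random grouping of these 15 libraries thus seldom gives as many, though 100 splits cannot show how seldom. It also takes the libraries as independent, and the labels do not state that each came from a separate rat.

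Against Sham, 6328 genes changed in J, 1125 in P and 1615 in PJ. By separate tests 58 genes in PJ were higher and 18 lower than in both Sham and OVX, with 5 and 15 in J and 3 and 2 in P. By 1 joint test per gene in limma there were 0 in each treatment (smallest adjusted p 0.281 in J, 1.00 in P and 0.675 in PJ), with 933 higher and 124 lower at an unadjusted p under 0.05 in PJ, 440 and 177 in J and 173 and 68 in P. These splits depended on the scale: they were 426 and 388, 270 and 339, and 89 and 181 with median-ratio scaling, and 980 and 103, 194 and 243, and 116 and 87 after rescaling to TPM.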
